A study of Danio rerio with 6 samples.

How the data were processed

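Total RNA from pools of 150 regenerating larval caudal fins was labelled by a 2-cycle protocol and hybridised to Affymetrix zebrafish arrays, per the labels' protocols, with 3 pools exposed to 1 uM beclomethasone and 3 control pools, all taken 1 day after amputation at 2 days post fertilization. The pools are described as separate replicates of 150 fins each; whether they came from separate clutches or days is not stated. The controls are called vehicle controls in the series description, while their own protocol describes a regeneration time course and mentions no vehicle. No batch or date is labelled, so a difference between the exposed and the control experiment cannot be told apart from the exposure.

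The values deposited by the authors are read here as a linear ratio per probe set. GCRMA, a background correction and summary method for probe intensities, is named per the submitters' processing notes. The later division is not given in the sources used here and was read from the values: the median of a probe set's 6 values was 1, within 1e-06, for 12601 of 15617 probe sets and below 1 for 3015, as a minimum divisor for dim probe sets would give. The ratios ran from 0.0567 to 91.4. They carry no level, so differences within a probe set can be compared between arrays and levels of different probe sets cannot, and signal over background is unknown.

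The design fixed before the data were examined assumed log2 levels, with a filter on dim probe sets (log2 above 4 on at least 3 arrays), a pseudocount of 1 for linear values and the brightest probe set per gene. The ratios needed another form: log2 of the ratio with no pseudocount, no filter, and the mean of a gene's probe sets. All 115 control probe sets were left out and 15502 were tested. The array annotation given with the data named 1 gene symbol for 10795 probe sets, several for 135 and none for 4572. Symbols were updated through Entrez numbers, which were found for 10711 probe sets and changed 1 symbol. Genes were named only from probe sets with 1 symbol, which gave 8793 genes, 1539 of them with several probe sets. Per1a, il1b and fgf20a, which were to be named in any case, were not matched to a probe set.

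Exposed and control pools were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), per probe set for the counts and the genes of largest change and per gene elsewhere. The fit was tested on simulated data for 15502 probe sets with 50 changed per size: 30% were recovered at 1.5-fold, 68% at 2-fold, 96% at 4-fold and 94% at 0.25-fold, and 5 of 149 calls were false. The simulated noise was independent between probe sets. In the real data the estimated inter-gene correlation was 0.422 for cell cycle and 0.587 for muscle genes, so this share of false calls need not hold there. The 31 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. With the correlation estimated from the residuals, none of the 15 lists called by camera passed; 10 of these 15 were among the 11 lists with a fry adjusted p under 0.05, and fry asks only whether a list's genes move on balance one way. Differences are exposed minus control, on the log2 scale, with standard errors from the fit. Exact permutation tests of 3 against 3 arrays cannot give a two-sided p below 0.1, so none is used as a verdict. The ribosomal list was built from symbols starting with rpl or rps and a digit, and so also holds a few genes of other function.

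The genes named were fixed by rule: the 10 largest rises and the 10 largest falls among passing probe sets with 1 named symbol and no overlap between the groups, up to 4 members of smallest p per list, and a set named in any case. Where a list had 5 or fewer genes that changed, all are named, the ones beyond the rule having been chosen after their values were seen. Alternatives were quantile normalization, centring of arrays on their medians, a variance trend with robust fitting, array weights, a replicate block, each array left out, a pseudocount of 16, a 2-fold threshold, genes as the unit, an estimated correlation and fry. Alternatives added after the values were seen were a pseudocount of 1, leaving out probe sets with a median below 1, every probe set as a list member, and leaving out both exposed pools with high apolipoprotein ratios.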

Results

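Gene expression was measured in the regenerating caudal fin of zebrafish larvae of the AB strain, 1 day after the fin had been amputated at 2 days post fertilization. Larvae had been kept in water with 1 uM beclomethasone, a synthetic glucocorticoid, or served as controls. The labels give 3 pools per group, each made of 150 fins, and each pool was hybridised to one Affymetrix zebrafish array. The comparison asks what a glucocorticoid does to gene expression in the early fin regenerate. The deposited values were read as ratios, for most probe sets to the probe set's own median over the 6 arrays. For the rest, nearly all with a median below 1, the divisor is not known. The data therefore give differences between pools and no expression level. The array medians of these ratios lay between 0.955 (exposed pool 1) and 0.998 (exposed pool 3). Log2 ratios correlated at 0.656 to 0.748 between exposed pools, at 0.583 to 0.778 between control pools and at 0.163 to 0.379 between the groups, across probe sets, which are not independent replicates. With 3 arrays per group, their number limits the precision of every value.

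Genes are ranked here among passing probe sets with 1 named gene symbol and no overlap between the groups. By this rule the genes that rose most in beclomethasone-exposed fins included regulators of glucocorticoid action and a receptor component of early development. The largest rise was that of hsd11b2, whose enzyme inactivates cortisol, with a log2 difference of 4.54 ± 0.19 (SE, n = 3 pools per group; 23.2-fold; adjusted p = 8.05e-05). The urea transporter gene slc14a2 rose by 4.42 ± 0.10 (21.4-fold; adjusted p = 3.84e-06), mgarpb by 4.39 ± 0.16 (21.0-fold; adjusted p = 6.22e-05) and tdgf1, which encodes the Nodal co-receptor of the Cripto family, by 3.96 ± 0.16 (15.6-fold; adjusted p = 8.05e-05). The glucocorticoid receptor co-chaperone gene fkbp5 rose by 3.13 ± 0.27 (8.74-fold; adjusted p = 0.00207). The remaining genes among the 10 largest rises were gldc (3.07, glycine cleavage), egln3 (3.04, a prolyl hydroxylase), desi1a (2.82), atp2a1l (2.69, related to a muscle calcium pump) and the sulfotransferase gene sult2st2 (2.65). The largest fall was that of the annexin gene anxa1b at -2.96 ± 0.27 (7.80-fold lower; adjusted p = 0.00212). It was followed by dkk3b (-2.75 ± 0.22), s100w (-2.69 ± 0.24), the transglutaminase gene tgm1l4 (-2.66 ± 0.50), the carboxylesterase gene ces2b (-2.63 ± 0.17) and the annexin gene anxa1d (-2.44 ± 0.37). Runx3 (-2.44 ± 0.44), b3gnt3.1 (-2.18 ± 0.11), the desmosomal plakophilin gene pkp1b (-2.11 ± 0.14) and mboat1 (-1.97 ± 0.22) came next. The adjusted p of these lay between 0.000219 and 0.0272. A further probe set of runx3 gave -0.57 (adjusted p = 0.387), and the mean of its probe sets lost its call without any 1 exposed pool or control pool 2 or 3. The call of tgm1l4 was lost without any 1 of the exposed pools.

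**Figure D1:**
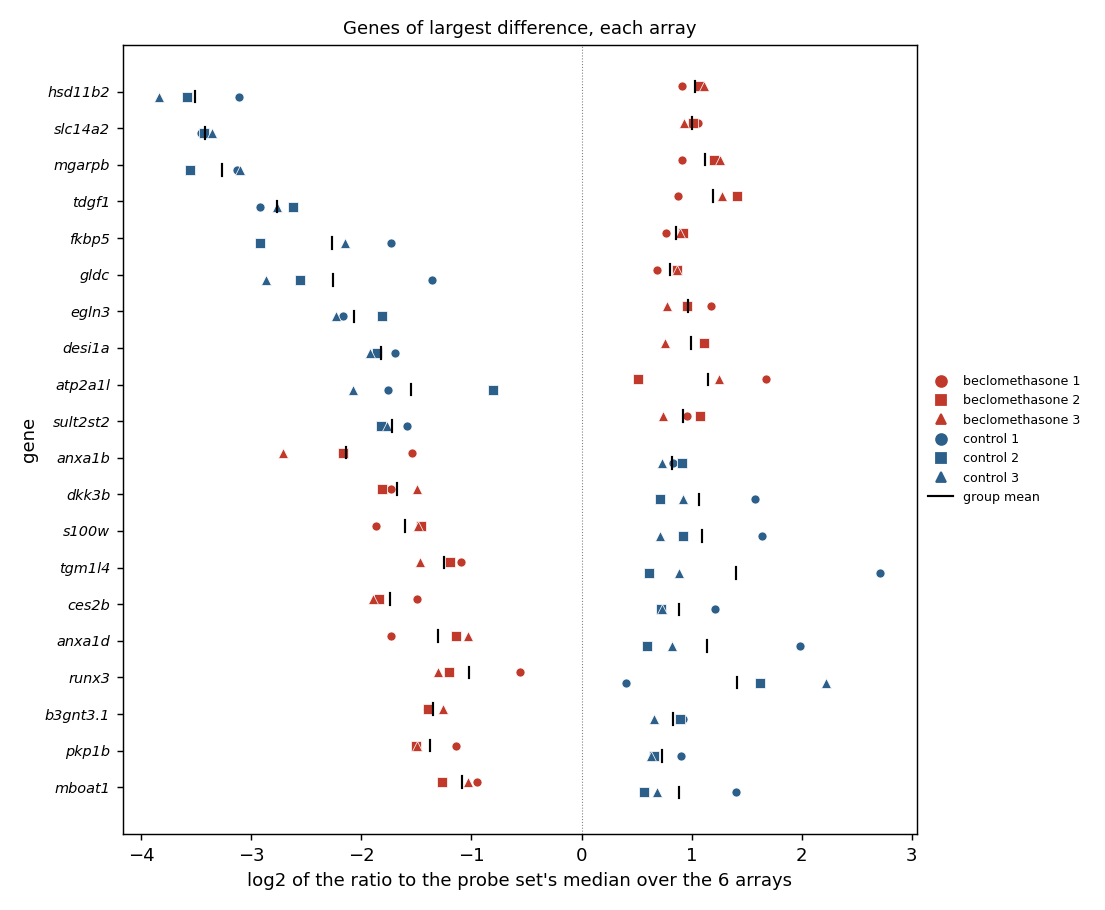
Log2 of the ratio to the probe set's median over the 6 arrays for the 10 probe sets of largest rise and the 10 of largest fall, one symbol per array, with short bars at the group means (n = 3). The 3 exposed and the 3 control arrays did not overlap for any of the 20, with control ratios of hsd11b2 between 0.0699 and 0.116 and exposed ratios between 1.88 and 2.16.

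Over all 15502 probe sets tested with limma, 446 were higher and 502 lower in exposed fins at an adjusted p under 0.05. At least 2-fold differences made up 207 of the higher and 163 of the lower ones. By gene, 373 of 8793 were higher and 403 lower. The groups did not overlap for 26.3% of all probe sets, where chance gives 10%. The counts fell to 199 higher and 217 lower without exposed pool 1, 176 and 204 without exposed pool 2, 187 and 180 without exposed pool 3, 178 and 235 without control pool 3, and the lower count to 262 without control pool 2. Leaving out exposed pools 1 and 2 together, a choice made after the apolipoprotein values of these pools had been seen, left 2 higher and 2 lower in limma (3 and 2 by gene; 2267 at an unadjusted p under 0.05). Slc14a2 (4.34), mgarpb (4.53), tdgf1 (4.05) and anxa1b (-3.54) still passed.

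Many of the genes known as targets of the glucocorticoid receptor rose. Of 41 measured, 18 rose and 1 fell over all genes, and 22 rose and 1 fell when adjusted over the list alone, with a list median of 0.48. Besides hsd11b2 and fkbp5, the members of smallest p were glula, which encodes a glutamine synthetase (1.84 ± 0.15, adjusted p = 0.00141), and ddit4, an inhibitor of growth signalling (2.40, exposed ratios 1.56 to 2.73 against 0.367 to 0.438). The glucocorticoid-induced gene tsc22d3 rose by 1.66 ± 0.18 (adjusted p = 0.00284) and klf9 by 2.23 ± 0.40 (adjusted p = 0.019). The single member that fell was cisha (-1.36 ± 0.25), of the cytokine signalling suppressor family. The receptor gene nr3c1 itself had a value of -0.42 ± 0.18 (adjusted p = 0.202) and pck1 one of 0.20 ± 0.13 (adjusted p = 0.402). The list lay higher than other genes in camera (adjusted p = 2.08e-09; adjusted p = 0.143 with an estimated correlation), and its per-array medians were 0.14 to 0.26 in exposed and -0.37 to -0.33 in control pools. The call of klf9 was lost without any 1 exposed pool or control pool 3, and that of cisha without exposed pool 2 or 3, while 3 targets fell without control pool 1.

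Most of the cell cycle genes measured fell. Of 80 measured, 50 fell and none rose over all genes, 64 fell when adjusted over the list alone, and the list median was -0.82. The falls of smallest p were those of the condensin gene ncapd3 (-1.58 ± 0.15), the mitotic kinesin gene kif11 (-1.33 ± 0.14), cks1b (-1.25 ± 0.10) and the DNA ligase gene lig1 (-1.14 ± 0.11), each passing without any 1 of the 6 arrays. The list lay lower than other genes in camera (adjusted p = 1.07e-31; adjusted p = 0.318 with an estimated correlation). Per-array medians were -0.71, -0.37 and -0.27 in exposed pools 1 to 3 and 0.21, 0.43 and 0.31 in the control pools. Markers of skeletal muscle went the other way, with medians of 0.67, 0.02 and 0.11 in the exposed pools and -1.21, -0.01 and -0.94 in the control pools. Exposed pool 1 had the highest muscle median and the lowest cell cycle median. The control pools did not share this inverse order: control pool 2 had their highest median in both lists and control pool 1 their lowest. The number of cell cycle genes that fell was 30 to 33 without any 1 exposed pool, 32 without control pool 2 and 30 without control pool 3.

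Epidermal genes fell more often than they rose. Of 55 measured, 15 fell and 3 rose over all genes, 20 fell and 4 rose when adjusted over the list alone, and the median was -0.25. The falls included pkp1b, anxa1b, the sciellin gene scel (-1.08 ± 0.11) and icn2 (-1.63 ± 0.16). The 3 that rose, named after their values were seen, were the keratin genes krt94 (1.47 ± 0.15) and krt18a.1 (0.74 ± 0.11) and the plectin gene plecb (0.76 ± 0.18, lost without exposed pool 2 or 3 or control pool 2 or 3). The list lay lower in camera (adjusted p = 1.54e-06; adjusted p = 0.389 with an estimated correlation). The number of epidermal genes that fell was 9 without exposed pool 3. Ionocyte genes, of the salt-transporting cells of the skin, rose in 6 of 21 and fell in 1, with the same counts when adjusted over the list alone. Besides hsd11b2, which this list also holds, the claudin gene cldn3c rose by 0.87 ± 0.12 and the Delta ligand gene dla by 1.51 ± 0.28, while the carbonic anhydrase gene ca2 fell by 1.39 ± 0.20 on the log2 scale. The ionocyte list median was 0.24 (camera adjusted p = 0.0158; 0.115 without control pool 1; adjusted p = 0.318 with an estimated correlation) and 0.15 without control pool 3. The call of dla was lost without exposed pool 2 or control pool 3, and the number of ionocyte genes that rose was 3 without exposed pool 1 and 2 without exposed pool 2 or control pool 3.

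Genes of the blastema and of early regeneration did not move one way. Of 39 measured, 7 rose and 2 fell over all genes, and 8 rose and 4 fell when adjusted over the list alone. Besides tdgf1, rises were found for the midkine gene mdkb (1.05 ± 0.19), the activin subunit gene inhbaa (0.52 ± 0.09) and the hedgehog ligand gene shha (0.77 ± 0.14). Falls were found for the nucleosome-binding protein gene hmgn2 (-0.98 ± 0.12) and the mitotic kinase gene ttk (-0.87 ± 0.21). The list median was -0.006 (-0.035 without exposed pool 2, 0.01 without exposed pool 1, 0.014 without control pool 2 and 0.022 without control pool 3) and the mean 0.12 (camera adjusted p = 0.753). The retinoic acid synthesis gene aldh1a2 had a value of -0.54 ± 0.14 (adjusted p = 0.0518), msx1b of -0.23 ± 0.14 (adjusted p = 0.379), junba of 0.21 ± 0.19 (adjusted p = 0.571) and junbb of -0.31 ± 0.24 (adjusted p = 0.505). Among 42 genes of TGF-beta, activin, Nodal and BMP signalling, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.093). Tdgf1, inhbaa, ccn2a (0.85 ± 0.14), the BMP antagonist gene nog1 (0.60 ± 0.12) and ccn1 (0.44 ± 0.09) rose, and the pseudoreceptor gene bambia fell by 0.95 ± 0.16 on the log2 scale. Wnt signalling genes showed 2 rises, wnt4b (0.83 ± 0.17) and wif1 (0.70 ± 0.17), and 2 falls, dkk3b and sp8b (-0.62 ± 0.11), among 37 (3 and 2 adjusted over the list alone; camera adjusted p = 0.688). The Wnt target genes axin2 and lef1 had values of -0.05 ± 0.13 (adjusted p = 0.882) and -0.31 ± 0.28 (adjusted p = 0.59). No gene of FGF signalling passed in limma among 22, over all genes or adjusted over the list alone, where 1 was higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.974), but 2 rose without control pool 1. Of the genes named as passing here, only tdgf1, dkk3b and hmgn2 kept the call without any 1 array. Bambia lost it without exposed pool 2, ccn2a without exposed pool 3 or control pool 3, and the others without at least 2 of the exposed pools and at least 1 of control pools 2 and 3. The number of blastema and early regeneration genes that rose was 2 or 3 without any 1 exposed pool or control pool 2 or 3, and 4 of them fell without control pool 1. For TGF-beta family genes it was 3 without exposed pool 1 or control pool 2, 2 without exposed pool 2 and 1 without exposed pool 3 or control pool 3.

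Fin fold mesenchyme genes had a median of 0.05 (camera adjusted p = 0.385; 0.10 without exposed pool 1, 0.12 without control pool 1, and 0.02 to 0.03 without any 1 other array), with 6 rises and 1 fall among 34 and 8 and 2 adjusted over the list alone. They included the vimentin gene vim (1.12 ± 0.17), the chemokine gene cxcl12a (0.92 ± 0.16), hoxd11a (1.01 ± 0.21) and the collagen gene col1a2 (0.49 ± 0.10), and the fall was that of snai1a (-0.49 ± 0.11). Of 41 extracellular matrix genes, 4 rose and 1 fell, and 10 rose and 2 fell when adjusted over the list alone. Efemp2b rose by 1.17 ± 0.12, col1a2, matn4 (0.39 ± 0.09) and col11a1a (0.39 ± 0.09) also rose, and col14a1a fell by 1.15 ± 0.20 on the log2 scale. The matrix list had a median of 0.11, or 0.19 without exposed pool 1 (camera adjusted p = 0.0422, between 0.0605 and 0.086 without exposed pool 2 or 3 or control pool 2 or 3, and adjusted p = 0.318 with an estimated correlation). Among 27 matrix remodelling enzymes and inhibitors, 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.208). The membrane metalloproteinase genes mmp14a (-0.65 ± 0.11) and mmp14b (-0.70 ± 0.11), the inhibitor gene timp2a (-0.62 ± 0.11) and the cathepsin gene ctsk (-1.05 ± 0.25) fell, and the collagen prolyl hydroxylase gene p4ha1b rose by 1.11 ± 0.18. Only vim, efemp2b and p4ha1b kept their calls without any 1 array. Mmp14a lost its call without exposed pool 2 or 3, mmp14b without exposed pool 1 or 3, col14a1a without exposed pool 1 or control pool 3, and the others without at least 2 of the exposed pools and at least 1 control pool. The number of mesenchyme genes that rose was 1 or 2 without any 1 exposed pool or control pool 3, and that of matrix genes 1 without these and 2 without control pool 2. Of the remodelling genes 1 fell without exposed pool 1 or 2, 0 without exposed pool 3 and 8 without control pool 1, where 3 rose.

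A few macrophage genes were lower in exposed fins, and other leukocyte groups differed between the control pools themselves. Of 18 macrophage genes, 3 fell over all genes, namely grna (-1.05 ± 0.21), lgals9l1 (-0.67 ± 0.15) and ctsk, which the remodelling list also holds, and 1 rose and 3 fell when adjusted over the list alone. The macrophage median was -0.27, or -0.48 without control pool 1 (camera adjusted p = 0.0167; adjusted p = 0.413 with an estimated correlation), and the call was lost without control pool 3 (adjusted p = 0.062). Of 13 inflammation and NF-kB genes, caspa rose (0.47 ± 0.09) and caspb (-0.66 ± 0.15) and irf1b (-1.33 ± 0.32) fell, 1 rose and 4 fell when adjusted over the list alone, and the list did not pass (median -0.17, camera adjusted p = 0.0643; 0.0495 without exposed pool 1 and 0.0485 without exposed pool 2). That median was -0.28 without exposed pool 1, -0.29 without control pool 1 and -0.08 without control pool 2. The collagenase gene mmp13a had a value of -1.58 ± 0.48 (adjusted p = 0.0906) and mmp9 one of -0.50 ± 0.46 (adjusted p = 0.603). Of 8 neutrophil genes, the lysozyme gene lyz (1.57 ± 0.32, adjusted p = 0.0286) and the chemokine receptor gene cxcr4b (0.73 ± 0.12) rose, also when adjusted over the list alone. The myeloperoxidase gene mpx had a value of -0.18 ± 0.16 (adjusted p = 0.574), and the list median was -0.15 with a mean of 0.04 (camera adjusted p = 0.974, direction down). That direction turned up without exposed pool 3 or control pool 2 or 3. The neutrophil median was -0.013 without control pool 2 and -0.066 without control pool 3, and 2 neutrophil genes fell without control pool 1. Of 11 pan-leukocyte genes, only cxcr4b rose, over all genes and adjusted over the list alone (median -0.29, camera adjusted p = 0.139), with medians of -0.62 without control pool 1 and -0.16 without control pool 2. Of 29 interferon and antigen presentation genes, 4 fell, with the same count adjusted over the list alone, namely b2m (-1.55 ± 0.23), mhc1zba (-0.95 ± 0.13), irf1b and ifi30a (-0.64 ± 0.14). The interferon median was -0.004 (camera adjusted p = 0.0643). With 1 array left out it ran from -0.068 without control pool 2 to 0.011 without exposed pool 1. Control pool 1 stood apart from control pools 2 and 3 in these groups: pan-leukocyte medians were -0.13, 0.50 and 0.44 in control pools 1 to 3 and -0.13, 0.05 and -0.15 in exposed pools 1 to 3. The ratios of lcp1 in the control pools were 0.858, 3.42 and 3.15. Without control pool 1 the camera adjusted p was 2.86e-05 for macrophage, 0.000156 for pan-leukocyte, 0.000737 for inflammation and 0.00666 for interferon genes, all lower, with 8 macrophage, 6 pan-leukocyte and 5 inflammation genes falling. No macrophage gene fell without any 1 exposed pool or control pool 2 and 1 fell without control pool 3, and 1 or 2 interferon genes fell without exposed pool 1 or 3 or control pool 2 or 3. Of the genes named as passing here, mhc1zba kept the call without any 1 array, b2m lost it without exposed pool 3, cxcr4b without exposed pool 1 or 2, and the others without at least 2 of the exposed pools and at least 1 of control pools 2 and 3.

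**Figure D2:**
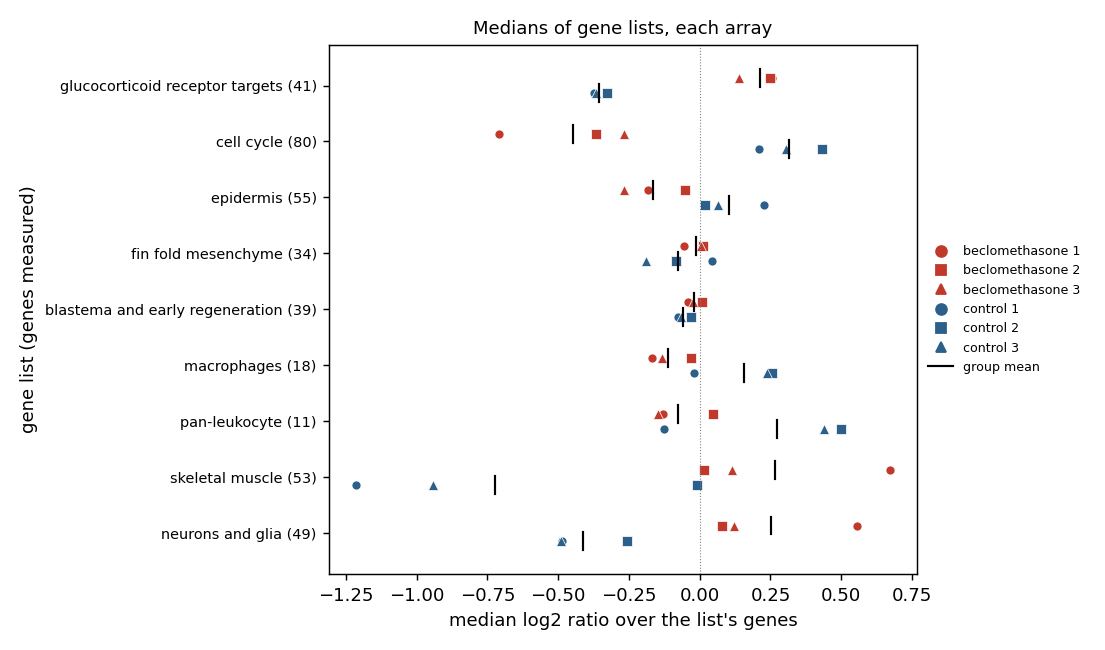
Median log2 ratio over the measured genes of 9 gene lists fixed in advance, one symbol per array, with short bars at the group means (n = 3). The glucocorticoid target medians lay at 0.14 to 0.26 in exposed and -0.37 to -0.33 in control pools. The skeletal muscle median of control pool 2 (-0.01) lay near that of exposed pool 2 (0.02), and the pan-leukocyte median of control pool 1 (-0.13) near that of exposed pool 1 (-0.13).

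Some genes of glucose, amino acid and lipid metabolism rose, while most did not pass. Of 32 gluconeogenesis and amino acid catabolism genes, 7 rose and none fell over all genes or adjusted over the list alone, where 10 were higher and 2 lower at an unadjusted p under 0.05. They were led by both glutamine synthetase genes, glula and glulb (0.85 ± 0.10), by the mitochondrial phosphoenolpyruvate carboxykinase gene pck2 (1.01 ± 0.13) and by the enolase gene eno3 (0.67 ± 0.13), which the muscle list also holds. The median was 0.23 (camera adjusted p = 0.0158; adjusted p = 0.318 with an estimated correlation) and 0.13 without exposed pool 3; 3 or 4 rose without any 1 exposed pool or control pool 3. Of 46 lipid genes, 7 rose over all genes and 8 when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.000718; adjusted p = 0.318 with an estimated correlation). In these genes 1 rose without exposed pool 1, 2 without exposed pool 2 or control pool 3 and 4 without control pool 2. The examples were angptl4 (0.81 ± 0.11), an inhibitor of lipoprotein lipase, the apolipoprotein gene apoc1 (0.99 ± 0.17), the pyruvate dehydrogenase kinase gene pdk2b (1.16 ± 0.22) and the fatty acid-binding protein gene fabp7a (0.90 ± 0.17). Of 11 cholesterol synthesis genes, only acat2 (-0.67 ± 0.14) changed, also when adjusted over the list alone (camera adjusted p = 0.565). Glula, glulb, pck2 and angptl4 kept their calls without any 1 array, apoc1 lost its call without exposed pool 1, and eno3, pdk2b, fabp7a and acat2 lost theirs without at least 2 of the exposed pools and at least 1 of control pools 2 and 3.

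The lipid list also held 4 apolipoprotein genes that stood apart in 2 of the exposed pools, named after their values were seen. The ratios of apobb.1 were 42.8 and 91.4 in exposed pools 1 and 2, 1.18 in exposed pool 3 and 0.489 to 0.816 in the control pools. Those of apoa1a were 13.8, 42.8 and 1.03 in exposed pools 1 to 3, those of apoa2 12.4, 61.0 and 1.16, and those of apoea 4.83, 35.4 and 0.977. None passed (apobb.1 4.61 ± 1.45, adjusted p = 0.101). Complement and acute phase genes, many of them made by the liver, rose in 4 of 47, with the same count adjusted over the list alone. They were socs3a (1.24 ± 0.14), the complement factor D gene cfd (2.11 ± 0.28), crp3 (2.14-fold, standard error 0.17 on the log2 scale) and c9 (0.54 ± 0.09, lost without exposed pool 2). The probe sets of c9 gave 0.316, 1.025 and 0.269 (limma adjusted p = 0.246, 0.0166 and 0.505). Of the complement and acute phase genes, 9 rose without exposed pool 3. The median of their list was 0.20 (camera adjusted p = 0.000173, and 0.318 with an estimated correlation) and 0.35 without exposed pool 1. With exposed pools 1 and 2 both left out it was 0.20 (camera adjusted p = 0.000334).

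**Figure D3:**
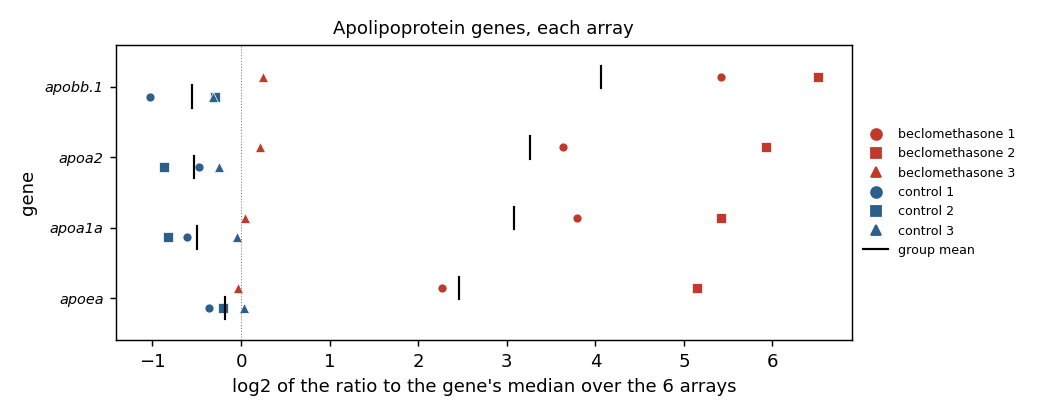
Log2 of the ratio to the gene's median over the 6 arrays for 4 apolipoprotein genes, one symbol per array, with short bars at the group means (n = 3). Exposed pools 1 and 2 lay far above the other arrays, with ratios of 42.8 and 91.4 for apobb.1 against 1.18 in exposed pool 3.

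Some markers of skeletal muscle and of neurons and glia were higher in exposed pools. Of 53 muscle genes, 6 rose over all genes and 23 when adjusted over the list alone, and the median was 0.94. Examples were atp2a1l, eno3, the myogenic factor gene myod1 (0.77 ± 0.15) and the myosin light chain gene myl10 (0.91 ± 0.20). The list lay higher in camera (adjusted p = 1.13e-10; adjusted p = 0.413 with an estimated correlation). The number that rose was 34 without control pool 2, whose muscle median (-0.01) lay near those of exposed pools 2 and 3, and 1 without any 1 exposed pool or control pool 3. Of 49 neuron and glia genes, 13 rose over all genes and 28 when adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.16e-10, and 0.318 with an estimated correlation). Per-array medians of this list were 0.557, 0.079 and 0.122 in exposed pools 1 to 3 and -0.487, -0.257 and -0.49 in control pools 1 to 3. The glial filament gene gfap rose by 1.25 ± 0.18, stmn2a by 1.53 ± 0.23, the vesicular inhibitory transmitter transporter gene slc32a1 by 1.67 ± 0.30 and the transcription factor gene isl1a by 1.08 ± 0.21. The number of neuron and glia genes that rose was 2 without exposed pool 2 or control pool 3, 6 without control pool 2 and 7 without exposed pool 1, exposed pool 3 or control pool 1. It was 5 with arrays centred on their medians, 6 with a pseudocount of 1 and 2 with a pseudocount of 16. Notochord and cartilage genes rose in 4 of 31 and fell in 1 (8 and 2 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0012; adjusted p = 0.318 with an estimated correlation; median 0.13 without control pool 1). They were shha, cmn (0.75 ± 0.15), matn4 and col11a1a as rises and runx3, which averaged -1.50 ± 0.32 over its 2 probe sets, as the fall. Of 18 blood vessel genes, plvapb (2.14-fold, standard error 0.23 on the log2 scale) rose over all genes and 4 rose when adjusted over the list alone. The group had a median of 0.22 (camera adjusted p = 0.0159; adjusted p = 0.413 with an estimated correlation; 0.0541 without control pool 1), and 5 rose without control pool 2. No erythrocyte gene passed among 23 in limma, over all genes or adjusted over the list alone, where 5 were higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.53), but 1 fell without control pool 1 and 1 rose without control pool 2. Atp2a1l, gfap and stmn2a kept their calls without any 1 array, slc32a1 and isl1a lost theirs without exposed pool 2 or control pool 3, and the other genes named as passing lost theirs without at least exposed pool 3 and control pool 3. Notochord and cartilage genes rose in 1 case without exposed pool 1 or control pool 2 and in 0 without exposed pool 3 or control pool 3.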

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

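The pseudocount of 1, the filter on probe set medians, every probe set as a list member and the removal of exposed pools 1 and 2 were chosen after the values were seen. The counts of higher and lower probe sets (446 and 502) and of shifted lists (15) stayed within 1.5 times under quantile normalization (460, 529, 14), array centring (358, 482, 14), a variance trend with robust fitting (551, 583, 15), pseudocounts of 16 (321, 377, 15) and 1 (385, 458, 15). So they did under removal of probe sets with a median below 1 (499, 536, 15) and with genes as the unit (373, 403). Both pseudocounts were added to ratios, which carry no level, so these settings do not test noise at low signal. Within lists counts moved more: 13 neuron and glia genes rose, but 5 under centring, 6 and 2 with pseudocounts of 1 and 16 and 4 with the replicate block. Rises of ionocyte genes went from 6 to 2 with a pseudocount of 16 and 3 with the replicate block, and those of mesenchyme genes from 6 to 3 and 2. Array weights gave 2 falling erythrocyte genes, and the variance trend 1 rise and 1 fall. Quantile normalization shared 885 of the 948 calls. Array weights gave 1073 and 1104 and 14 lists, without ionocytes (adjusted p = 0.0753), blood vessels (0.112) and heat shock (0.0901) but with inflammation (0.0346) and pan-leukocyte genes (0.0398); the cause was not tested. The stricter 2-fold threshold gave 207 and 163. Fits with an array left out gave 176 to 565 higher, 180 to 668 lower and 13 to 16 lists. Without exposed pools 1 and 2, which leaves 1 exposed array assumed to vary like the controls, 2 and 2 probe sets and 13 lists passed, without heat shock (adjusted p = 0.482), ionocytes (0.058) and matrix (0.12) but with inflammation (0.0243). With every probe set as a member 17 lists passed, without matrix (0.0612) but with inflammation (0.0211), interferon (0.048) and ribosomal genes (0.033). An estimated correlation left 0 lists (camera in limma; 11 by fry); the cause was not tested. The replicate block gave 200 higher and 236 lower probe sets, 418 of them shared, and 14 lists, the matrix list being the 1 lost (adjusted p = 0.0553). Deviations of same-numbered pools correlated at -0.209, -0.038 and 0.111, only number 3 correlating best with its own number. Pools of different number correlated at -0.245 to 0.265. With 3 pools per group these values cannot tell whether the numbers pair the pools. By scaling, the pigment list was lost under quantile normalization (adjusted p = 0.0641) and the heat shock list under centring (adjusted p = 0.0508). Of the genes named, axin2 turned positive under array weights (0.00), without exposed pool 3 (0.006) and without control pool 1 (0.06), from -0.158 to 0.06 over the arrays left out. Lef1 did so without control pool 3 (0.049; range -0.503 to 0.049), and fabp10a without exposed pool 1 (0.077; range -0.141 to 0.077) and without exposed pools 1 and 2 (0.134). None of these passed, and the cause was not tested. Genes were called by the mean of their probe sets, and for some genes named as passing a single probe set did not pass in limma. Such probe sets had adjusted p of 0.0899, 0.0732 and 0.233 for fosab and 0.696 for foxo3b. Others were found for caspb (0.364), inhbaa (0.192), col1a2 (0.151), jun (0.143), mmp14a (0.133) and glulb (0.0571). Planned filters on levels (log2 above 4 or 6) and the brightest probe set per gene were not run, since ratios carry no level, and signal over background is unknown.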

Other observations

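The test of yolk or liver RNA, those of induction and of dilution, the count of tissue list pairs, the hybridisation controls and the splits of the arrays were chosen after the results were seen. Both tests with muscle as a covariate were set before their results. A planned comparison of liver genes with all genes was replaced, since any list that rises with exposure would meet it.

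Among genes of xenobiotic metabolism, 3 rose and 3 fell of 45, with 4 and 3 when adjusted over the list alone (camera adjusted p = 0.857). The rises were those of the steroid sulfotransferase family genes sult2st2 and sult2st1 (2.13 ± 0.14, 4.38-fold, n = 3 pools per group), which kept their calls without any 1 array, and of gstp1.2 (0.75 ± 0.14). The falls were those of the glutathione transferase genes gstm.1 (-1.22 ± 0.12), gsto2 (-0.41 ± 0.10) and mgst3a (-0.47 ± 0.11). Of 44 p53 and apoptosis genes, 5 rose and 3 fell, with 9 and 5 when adjusted over the list alone (camera adjusted p = 0.672). The apoptosis inhibitor gene xiap rose by 1.52 ± 0.19 and birc2 by 0.40 ± 0.10, beside foxo3b (0.52 ± 0.09), tp53inp1 (0.90 ± 0.18) and mdm2 (0.57 ± 0.13). The mitotic survivin gene birc5a (-0.96 ± 0.14), bcl2l10 (-0.97 ± 0.16) and sesn3 (-0.65 ± 0.13) fell. Sult2st1, gstm.1, xiap and birc5a kept their calls without any 1 array; bcl2l10 lost it without exposed pool 3, and the others without each of the exposed pools and at least 1 control pool. In the p53 list 1 rose without any 1 exposed pool or control pool 2 or 3, 8 rose without control pool 1 and 1 fell without exposed pool 3, and 1 xenobiotic gene fell without any 1 exposed pool or control pool 2.

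Pigment cell genes rose in 4 of 27 and fell in 1, with the same counts when adjusted over the list alone. The melanin synthesis gene dct rose by 1.25 ± 0.13 and the neural crest gene foxd3 by 1.17 ± 0.24, beside bco1 (0.81 ± 0.17) and paics (0.60 ± 0.14), and the purine synthesis gene atic fell by 0.94 ± 0.11 on the log2 scale. The list median was 0.12 (camera adjusted p = 0.0252; adjusted p = 0.413 with an estimated correlation), and the call was lost without exposed pool 3 (0.067) or control pool 1 (0.0861). Heat shock and stress genes rose in 4 of 47, also when adjusted over the list alone, namely gadd45bb (0.78 ± 0.12), hsp90aa1.2 (1.18 ± 0.20), fosab (1.03 ± 0.24) and jun (0.73 ± 0.17). Their median was 0.15 (camera adjusted p = 0.0469; adjusted p = 0.318 with an estimated correlation). That call was lost without exposed pool 1 (0.185) and without control pool 1 (0.0861) or 3 (0.0572). Of 35 circadian clock genes, bhlhe40 fell by 0.97 ± 0.13 on the log2 scale and usp2a (0.70 ± 0.16), csnk1db (0.43 ± 0.10) and cry4 (0.81 ± 0.19) rose. The counts were the same adjusted over the list alone, with a median of 0.01 (-0.049 without exposed pool 3 and -0.035 without control pool 2) and a camera direction of down (adjusted p = 0.993). No ribosomal protein gene passed among 78 in limma, over all genes or adjusted over the list alone, and none did at an unadjusted p under 0.05. The ribosomal median was -0.06, or 0.014 without control pool 1, -0.031 without exposed pool 1 and -0.119 without control pool 3. The camera adjusted p was 0.0724, or 0.000346 without control pool 3 and 0.0485 without exposed pool 2. Dct, atic and bhlhe40 kept their calls without any 1 array, gadd45bb lost its call without exposed pool 3, hsp90aa1.2 without exposed pool 1 or 3, and the others without at least 2 of the exposed pools and at least 1 control pool. Pigment genes rose in 1 or 2 cases without any 1 exposed pool or control pool 2 or 3, heat shock genes in 1 without exposed pool 1, 0 without exposed pool 3 and 2 without control pool 3, and clock genes in 1 without exposed pool 1 and 0 without exposed pool 2 or 3 or control pool 2 or 3.

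The first pattern is that of the apolipoproteins in exposed pools 1 and 2, where the log2 excess of exposed pool 3 over the controls was 0.114 of that in pools 1 and 2 (median over the 4 genes, upper quartile 0.127). As the genes were picked for pools 1 and 2 and pool 3 is a single array, induction by beclomethasone cannot be told apart. RNA of yolk or liver tissue in these pools is a candidate explanation: among genes whose 2 highest arrays were both exposed, these were pools 1 and 2 for 14 of 29 complement and acute phase genes and for 25.3% of 2878 others (Fisher's exact test, odds ratio 2.75, 95% interval 1.22 to 6.14, p = 0.00874; genes are not independent). The fibrinogen gene fgg (ratios 2.49 and 7.60 in these pools, 0.613 to 1.13 elsewhere) belongs to this list. It was already counted in the test and adds nothing to it. The liver gene fabp10a, looked up after the first test, was not higher in these pools (0.809 and 1.01, 0.966 to 1.09 elsewhere). As its signal over background is unknown, this gene cannot decide on liver tissue. Of the 47 measured genes of the list, 4 are also in others. Yolk and liver tissue stay open, since the labels name only fins and the ratios give no level to set against them.

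The second pattern is the rise of muscle and nerve markers. It was assumed, and not tested, that pools with less fin would raise the markers of every other tissue alike. Of 15 pairs of tissue lists, 4 differed in their shift with no overlap between the groups, all 4 involving neurons and glia. Any such pair was first taken to argue against less fin in the exposed pools. The comparison with other splits of the arrays, which gave up to 5 pairs, was added after the 4 had been seen, and with it the matter cannot be told apart. The nerve gene rise had a median of 0.26 with the muscle list mean as a covariate and 0.55 without it. This was only just under the bound of 0.27 set in advance (quartiles 0.14 and 0.54). It shows that both lists varied together over the arrays and cannot tell whether muscle carried along was the cause. Exposed pool 2 and control pool 2, only 1 pair of arrays, had close muscle medians (0.015 and -0.009) and neuron and glia medians of 0.079 and -0.257. A response of these tissues to the glucocorticoid was not tested and stays open, and 2 muscle and 1 neuron genes are also in other lists.

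The third pattern is the fall of cell cycle genes. The lower quartile of fin fold mesenchyme genes (-0.16) lay above the upper quartile of cell cycle genes (-0.46), by 0.30, so the mesenchyme list did not share the fall. Dilution of fin tissue by other tissue would lower the mesenchyme list only if that tissue lacked its genes. This was not tested, and 14 of the 34 mesenchyme genes are also in other lists, so dilution cannot be told apart. With muscle content as a covariate the cell cycle median was -0.76 against -0.82 without it. The upper quartile of -0.39 missed the bound of -0.41 set in advance for excluding muscle content, and it is a spread over genes, not over arrays. Exposed pool 2 and control pool 2 had close muscle medians (0.015 and -0.009) and cell cycle medians of -0.366 and 0.431. That is only 1 pair of arrays, so a part played by muscle content cannot be told apart. Calls with the covariate, which also took up a degree of freedom, were 8 cell cycle genes, 11 glucocorticoid receptor targets and 121 genes in all; without it 50 cell cycle genes fell, 18 targets rose and 1 fell, and 373 genes rose and 403 fell in all. An origin of the control arrays in another experiment cannot be told apart from the exposure: hybridisation controls differed by -0.000733 (18 probe sets; exact permutation p = 1, smallest possible 0.1), but 0 labelled batches hold both groups. Proliferation itself was not measured.

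Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 948 probe sets and the highest of the others 0; for the lists the real split gave 15 and the highest of the others 9. In both cases 1 of the 10 splits gave a result as large, the real one.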
